A study of Mus musculus with 30 samples.

How the data were processed

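Total RNA of mouse caecum was sequenced in 30 libraries, 6 in each of 5 groups. The libraries belong to 2 experiments. An initial experiment (12 libraries) held uninfected mice with or without 3'-sialyllactose (3'SL), a human milk oligosaccharide given in the drinking water. A second experiment (18 libraries) held uninfected mice on the control diet, mice on the control diet infected with the whipworm Trichuris muris (Tm), and infected mice given 3'SL. Infected mice received 3 doses of 20 eggs, a trickle infection, and tissue was taken 35 days after the first dose. The groups were taken from the sample labels. The labels count mice per group, and p-values measure the spread between these samples. Cage, litter, sex, sequencing batch and time of day at harvest are not given in the sources used here.

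The authors deposited raw read counts per gene, with no normalization. Per the submitters' processing notes the genome build was GRCm39 and DESeq2 was used; the aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The values were whole numbers with totals of 33853434 to 42076740 per library. The table held 21899 gene identifiers, of which 3467 had no count in any library. Symbols were taken from GENCODE M21, which matched 21795 identifiers; 104 had no match and 102 shared a symbol with another identifier. That annotation belongs to an older build, so only names were used and no coordinates are given. A further 10 table entries were not analysed here. Reads of near-identical genes could be split or lost in counting, so values of the mast cell proteases (Mcpt1, Mcpt2, Mcpt9, Cma2, Tpsb2), Tgtp1, Reg3b and Reg3g, Defa24, Oas1a, the H2 genes, the globin genes and Ugt1a9, which shares exons with its neighbours, are uncertain. The same holds for genes that overlap an antisense gene, since strand is not stated.

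Tests were made in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 with a robust fit, TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and a Benjamini-Hochberg adjusted p under 0.05. The initial experiment was fitted alone. The comparisons among the 3 groups of the second experiment came from a fit of its 18 libraries, which share an estimate of the spread. The difference of the 3'SL effects between experiments came from a fit of all 30 libraries. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are TMM-normalized CPM, counts scaled to a common library total, as mean ± SD over 6 libraries unless stated. All adjusted p-values of genes are from edgeR unless another tool is named. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, in both directions, and adjusted over the 30 lists of each comparison. Camera was repeated with an estimated correlation, and fry was run beside it; fry tests whether the members of a list move one way on balance and does not compare the list with other genes. Of 494 list members, 479 were in the table; the plasma cell list could be tested on 6 genes, and Retnlb is in 2 lists. Where a group had no count, a fold is a lower bound set at 3 counts over the group; with 1 to 3 counts a ratio is given with its exact 95% interval. Intervals and floors cover counting error only.

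The groups, main tests, lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule took, for each of the first 3 comparisons, the 6 highest and 6 lowest fold changes among called genes with a mean CPM of at least 1, leaving out predicted genes and antigen receptor segments. Where no gene was called, it took the 3 smallest p-values in each direction. It added up to 3 members with the smallest p of each list that camera called, and Ifng, Nos2, Ido1, Il13, Muc2, Retnlb, Mcpt1 and Reg3g whatever their result. For the other comparisons it took the 3 highest and 3 lowest. All genes under the rule were put through every alternative setting in which they had an adjusted p. For length, the results give values for the first 2 of the members with the smallest p in each list; this shortening was decided after the data were seen and uses only the order of p. Some genes under the rule or in the lists are not reported here. Members of the sialic acid list and of the IL-17 and IL-22 list are named outside the rule, as are single genes in counts of 5 or fewer; they were chosen after their values were seen.

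The alternative settings were DESeq2 1.42.0, DESeq2-style (RLE) size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in at least 6 libraries, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Covariates for the level of the B cell list and of the adipose tissue list were added after seeing the data. Principal components were computed on log2 CPM of 12824 genes. Among the 75 pairs of libraries within groups, the chi-square per gene lay between 14.4 and 398, so no library was a copy of another. The fits were tested on simulated counts drawn from the means of the real genes. Each gene was drawn independently, without the variation that genes share in the real libraries. The shares recovered and the false calls therefore need not hold for the real data. In the design of the initial experiment (14765 genes, 12 libraries), 52.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, with 9 false calls (DESeq2, 39). In the design of the second experiment (15191 genes, 18 libraries), simulated for 3'SL in infected mice, the shares were 49.3%, 71.2% and 92.4%, with 15 false calls (DESeq2, 31).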

Results

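Bulk RNA sequencing of caecum gave 33853434 to 42076740 counts in each of 30 libraries. The groups are called initial control, initial 3'SL, uninfected control, infected control and infected 3'SL, and libraries carry numbers 1 to 6 within each. The first principal component held 64.9% of the variance. The uninfected controls of the second experiment lay between 14.5 and 31.7 on it, the infected controls between −62.1 and 22.9, and the infected 3'SL libraries between −83.1 and −47.5. The infected controls were not uniform. Libraries 3, 5 and 6 lay at −62.1, −56.9 and −49.9, within the range of the infected 3'SL libraries. Libraries 1, 2 and 4 lay at 22.9, −3.49 and −12.3. Mitochondrially encoded genes took 11.3% ± 0.35 of the counts in uninfected controls, 9.07% ± 3.28 in infected controls and 5.98% ± 0.91 in infected 3'SL libraries.

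**Figure D1:**
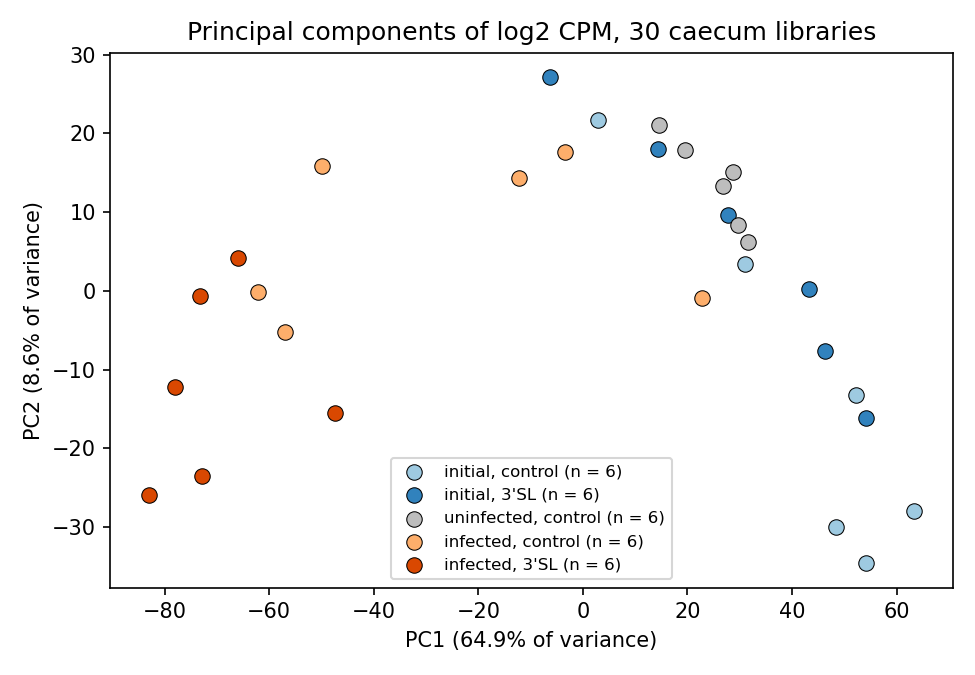
Scores of the 30 libraries on the first (64.9% of variance) and second (8.6%) principal component of log2 CPM; each point is a library, coloured by group (n = 6 each). The infected 3'SL libraries lie between −83.1 and −47.5 on the first component and the infected controls between −62.1 and 22.9. Infected control libraries 3, 5 and 6 lie within the range of the infected 3'SL libraries.

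The initial experiment asked what 3'SL does in uninfected mice. No gene passed: edgeR called 0 of 14880 genes, with 1056 at an unadjusted p under 0.05 against 744 by chance and a smallest adjusted p of 0.687. The rule took the 3 genes with the smallest p-values in each direction. Saa1, an acute phase protein, was at 82.8 ± 14.9 CPM in controls and 146 ± 44.6 with 3'SL (log2 fold change 0.81 ± 0.18 SE, n = 6 each). Pspc1 was 0.34 ± 0.08 and Trdmt1 0.54 ± 0.13 higher, while Slc5a3 (−0.51 ± 0.10), Hspa4l (−0.31 ± 0.06) and Bag3 (−0.38 ± 0.08) were lower, all with an adjusted p of 0.687. DESeq2 called 5 genes, named here after their values were seen: Pla2g4c, Saa1, 1190002N15Rik, Slc5a3 and Hspa4l. Pla2g4c, the largest of these by fold (−5.16), stood at 121 CPM in control library 3 and at 0.701 to 23.8 CPM in the other controls. Among the genes fixed by name, Muc2, the main secreted mucin, had a log2 fold change of −0.41 ± 0.19 (adjusted p = 0.698), Retnlb −0.36 ± 0.19 (0.717), Mcpt1 −1.33 ± 0.61 (0.702), Reg3g 1.05 ± 1.06 (0.837), Nos2 0.13 ± 0.32 (0.923) and Ido1 0.13 ± 0.24 (0.899). Ido1 turned to −0.0234 without initial 3'SL library 4 and to −0.0093 without control library 1. Ifng and Il13 were below the filter, with at most 0.0475 ± 0.0914 CPM in either group.

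As groups of genes, 14 of the 30 lists stood apart from other genes in camera, although none of their members was called singly. B cell genes had a median log2 fold change of 1.02 over 14 members, with Bank1 at 1.02 ± 1.04 (adjusted p = 0.699 with an estimated correlation). Bank1 ranged from 1.54 to 53.6 CPM among control libraries and from 4.28 to 69.1 CPM with 3'SL. T and NK cell genes (median 0.56, 21 members, Klrb1c 0.62 ± 0.34, Ncr1 0.75 ± 0.47; 0.711), MHC class II genes (0.53, 11 members, Ctss 0.18 ± 0.09, H2-DMb1 0.47 ± 0.33; 0.699) and interferon-gamma response genes (0.13, 30 members, Psmb9 0.49 ± 0.31, Psmb8 0.57 ± 0.43; 0.752) were on the higher side. Cell cycle genes (0.13, 26 members, Bub1 0.33 ± 0.14, Aurkb 0.26 ± 0.12; 0.711) and red blood cell genes (0.46, 4 members, Hbb-bt 0.63 ± 0.27, Hbb-bs 0.50 ± 0.24; 0.699) were also on the higher side. Each last number is the adjusted p with an estimated correlation. These lists moved beside the B cell list, whose level varied widely within both groups. Without 3'SL library 2 the median was 0.41 for B cell genes, 0.12 for T and NK cell genes, 0.13 for MHC class II genes and 0.0133 for interferon-gamma response genes. Without control library 5 these medians were 2.46, 1.01, 1.09 and 0.45. The interferon-gamma median was also 0.22 and 0.23 without 3'SL libraries 4 and 6 and 0.0435 without control library 6. The cell cycle median was 0.0615 without 3'SL library 3 and 0.0621 without control library 6, and the red blood cell median was 0.27 without control library 4.

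On the lower side were immediate early and stress genes (median −0.30, 14 members; Fosb −1.06 ± 0.28, Hspa1b −1.12 ± 0.28), of which 4 passed when adjusted over the list alone, with an adjusted p of 0.457 under an estimated correlation. Enteric neuron and glia genes had a median of −0.29 (Nos1 −0.46 ± 0.15, Tubb3 −0.38 ± 0.14; adjusted p = 0.699 with an estimated correlation), and fibroblast genes −0.23 (Mmp2 −0.33 ± 0.11, Pdgfra −0.23 ± 0.09; 0.699). The median was −0.15 for goblet cell genes (Spdef −0.29 ± 0.09, Fcgbp −0.35 ± 0.15; 0.699), −0.11 for crypt stem cell genes (Sox9 −0.39 ± 0.13, Lgr5 −0.25 ± 0.11; 0.699) and −0.15 for mitochondrially encoded genes (mt-Nd4 −0.25 ± 0.18, mt-Nd2 −0.19 ± 0.17; 0.752). It was −0.06 for tight junction genes (Tjp1 −0.21 ± 0.09; 0.711) and −0.87 for mast cell genes (Ms4a2 −1.40 ± 0.58, Mcpt9 −1.44 ± 0.60; 0.711). The mast cell median was −0.26, −0.50, −0.40 and −0.37 without 3'SL libraries 2, 4, 5 and 6, and −0.51, −0.15 and −0.57 without control libraries 2, 3 and 4. The mitochondrial median was −0.0304, −0.26 and −0.10 without 3'SL libraries 2, 3 and 6 and −0.0811 without control library 2. The tight junction median was −0.0274 and −0.0936 without 3'SL libraries 2 and 4, and −0.0296 and −0.11 without control libraries 2 and 5. The goblet cell median was −0.0957 without 3'SL library 2, and the crypt stem cell median −0.0691 without 3'SL library 5 and −0.0680 without control library 4. Fry called none of the 30 lists (smallest adjusted p 0.189).

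Of the 14 list calls, 10 were lost when a library was left out. The T and NK cell list (adjusted p = 0.111) and the goblet cell list (0.0514) were lost without 3'SL library 2. The cell cycle list was lost without 3'SL library 3 (0.139) or control library 6 (0.146), the crypt stem cell list without 3'SL library 5 (0.0547) or control library 4 (0.0530), and the fibroblast list without control library 6 (0.0563). The interferon-gamma list was lost without any of 3'SL libraries 2, 3 and 5 or control libraries 3, 4 and 6 (0.0547 to 0.673), the mast cell list without any of 3'SL libraries 2 to 6 or control libraries 2 to 4 (0.0577 to 0.388), and the mitochondrial list without any of 3'SL libraries 2, 4 and 6 or control libraries 2 to 4 (0.0547 to 0.742). The red blood cell list was lost without any of 3'SL libraries 2, 3 and 5 or control libraries 3 and 4 (0.0506 to 0.0629), and the tight junction list without 3'SL libraries 2 or 5 or control libraries 2 to 4 (0.0547 to 0.399).

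The other lists missed the camera threshold in uninfected mice, with these adjusted p-values: type I interferon response 0.308, type 2 response 0.791, tuft cell 0.260, antimicrobial and acute phase 0.643, absorptive colonocyte 0.978, enteroendocrine cell 0.700 and plasma cell 0.0618. Further ones were macrophage and monocyte 0.701, granulocyte 0.260, IL-17 and IL-22 axis 0.643, smooth muscle 0.326, adipose tissue 0.929, sialic acid metabolism 0.643, cholesterol synthesis 0.0743, fatty acid oxidation 0.0618 and circadian clock 0.0625. Adjusted over the list alone, 1 member passed in each of the antimicrobial, macrophage, and IL-17 and IL-22 lists. Median and test differed in sign for the type 2 list (median −0.06), the adipose list (−0.01), the absorptive list (0.01) and the macrophage list (0.04). The enteroendocrine list had a median of 0.0574 and a mean of −0.0019.

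The second experiment asked first what Tm infection does on the control diet. Infection changed 4008 of 15290 genes, 2425 upward and 1583 downward, with 863 and 127 of them by at least 2-fold. Mast cell genes rose most: 11 of 11 tested members were called (11 when adjusted over the list alone; median log2 fold change 6.29; adjusted p = 0.353 with an estimated correlation). The mast cell protease Mcpt1 (ENSMUSG00000022227) went from 9.77 ± 4.11 to 1797 ± 1454 CPM (185-fold, log2 7.53 ± 0.78 SE, adjusted p = 3.16e-05), and no infected library was below 639 CPM. The highest fold changes by the rule were Cma2 (10.94 ± 1.20), Pla2g4c (8.43 ± 1.13), the IgE receptor chain Fcer1a (7.86 ± 0.84) and Mcpt9 (7.59 ± 0.76). They also included S100a9, at least 165-fold higher, and Defa24, at least 82.7-fold higher, neither with a count in uninfected controls. The lowest were the calcium channel Trpv6 (−4.78 ± 0.89), Plin1 (−4.56 ± 0.89), Adipoq (−4.47 ± 1.03), Car3 (−4.13 ± 0.83), Retn (−4.07 ± 1.00) and Cfd (−3.89 ± 1.17). Defa24 was not called without infected control library 4 (at least 40.5-fold, adjusted p = 0.0512), S100a9 without library 5, which held 477 of its 526 counts (at least 18.2-fold, 0.0579), and Cfd without infected control library 6 (0.0520) or uninfected control library 4 (0.0523). Trpv6 was −6.96 without infected control library 1, and Pla2g4c 7.68 without infected control library 3 and 9.42 without uninfected control library 1. Without uninfected control library 4, Plin1 was −3.89, Adipoq −3.85, Car3 −3.53 and Retn −3.43, and without infected control library 4 Plin1 was −5.20 and Retn −4.81.

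Immune gene groups rose together with infection. Of 31 interferon-gamma response genes 30 rose (31 adjusted over the list alone), with a median of 2.90 (adjusted p = 0.484 with an estimated correlation): Psmb8 by 1.76 ± 0.35, and the chemokine Cxcl9 (ENSMUSG00000029417) by 7.15 ± 1.48. The median of the list was 1.64 without infected control library 5. Cxcl9 was at 3.93, 6.37, 92.0, 9.78, 2416 and 74.0 CPM in infected control libraries 1 to 6, against 1.47 to 4.60 CPM in uninfected controls. Ifng rose by 5.58 ± 1.43 (adjusted p = 0.0112) and Nos2, the inducible nitric oxide synthase, by 3.65 ± 1.09 (0.0224), while Ido1 did not pass (1.84 ± 0.76, 0.0798). Without infected control library 5, Ifng (2.77, adjusted p = 0.0662) and Nos2 (1.69, 0.155) were not called. Without library 4, Ido1 was (2.09, 0.0369), as it was in DESeq2 (1.83, 0.0487). Ifng was 6.25 without uninfected control library 1. Without infected control library 5, Cxcl9 was 3.62, Oasl2 1.43 and Rtp4 1.09. Type I interferon response genes rose in 12 of 16 cases (13 adjusted over the list alone; Oasl2 2.34 ± 0.55, Rtp4 1.94 ± 0.51; adjusted p = 0.601 with an estimated correlation; fry 0.124). MHC class II genes rose in 10 of 11 (11 adjusted over the list alone; H2-DMb1 1.98 ± 0.38, Cd74 1.32 ± 0.27; 0.368 with an estimated correlation).

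Type 2 response genes rose in 10 of 14 cases (10 adjusted over the list alone), among them the chemokine Ccl8 (4.15 ± 0.52) and Il1rl1, the IL-33 receptor (1.70 ± 0.25), with an adjusted p of 0.368 under an estimated correlation. Il13 was 36.2-fold higher (95% interval 9.68 to 304, from 2 against 77 counts, adjusted p = 0.0125). Both uninfected counts lay in uninfected control library 6. Without that library the fitted log2 value went from 4.73 to 6.65 (adjusted p = 0.0270) and depends on the prior count. T and NK cell genes rose in 21 of 23 (22 adjusted over the list alone), with the granzymes Gzma at 6.67 ± 0.76 and Gzmb at 5.92 ± 0.86. Macrophage genes rose in 14 of 16 (15, with Itgax 1.85 ± 0.19, Itgam 1.44 ± 0.24) and granulocyte genes in 9 of 12 (10, with Csf3r 2.64 ± 0.55, Ly6g 4.23 ± 0.95). Of the antimicrobial and acute phase genes 7 rose and 1, Dmbt1, fell of 14 (8, with Ang4 5.11 ± 0.69, Itln1 5.20 ± 0.86), and their median of 1.43 was the same with genes lacking counts set at their bound. The antimicrobial median was 0.82 without infected control library 3. The adjusted p of these 4 lists was 0.368 with an estimated correlation. B cell genes rose in 11 of 14 (13, with Ms4a1 1.24 ± 0.29, Cxcr5 1.24 ± 0.31) and cell cycle genes in 13 of 26 (16, with Cenpf 0.70 ± 0.11, Mki67 0.71 ± 0.14), both with an adjusted p of 0.498 under an estimated correlation. Gzmb was 4.86 and Csf3r 1.76 without infected control library 5, and Ly6g 3.06 without library 3. Counts in brackets without another label are adjusted over the list alone. Retnlb rose by 2.19 ± 0.37 (adjusted p = 0.00143) and Muc2 by 0.82 ± 0.23 (0.0163), while Reg3g did not pass (1.89 ± 0.84, 0.102).

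Absorptive colonocyte genes fell in 6 of 20 cases and rose in 1, Ceacam20 (7 adjusted over the list alone): the phosphate transporter Slc20a1 fell by 1.70 ± 0.29 and the sodium channel subunit Scnn1b by 2.60 ± 0.45 on the log2 scale. Fatty acid oxidation genes fell in 14 of 20 and rose in 1, Ffar2 (16 adjusted over the list alone; Pparg −0.83 ± 0.17, Acadvl −0.59 ± 0.15), and tight junction genes fell in 6 of 16 (10, with Cgn −0.65 ± 0.11, Tjp3 −0.46 ± 0.12). Circadian clock genes fell in 9 of 15 and rose in 3, namely Arntl, Per1 and Cry1 (12, with Tef −1.43 ± 0.23, Dbp −2.39 ± 0.41). These 4 lists had an adjusted p of 0.368 with an estimated correlation. Dbp was at 22.1 to 38.6 CPM in uninfected controls of this experiment, 1.13 to 14.1 CPM in infected controls and 3.11 to 28.8 CPM in the uninfected mice of the initial experiment. Adipose tissue genes fell in 11 of 11 (11, with Lpl −1.42 ± 0.23, Cd36 −1.12 ± 0.20; adjusted p = 0.360 with an estimated correlation). Adipoq was at 1.45 to 29.0 CPM in uninfected controls of this experiment, at 0 to 1.16 CPM in infected controls and at 0 to 8.74 CPM in the initial experiment. The 13 mitochondrially encoded genes had a median of −0.28 with none called singly (mt-Atp8 −0.44 ± 0.20, mt-Co1 −0.47 ± 0.23; adjusted p = 0.601 with an estimated correlation; fry 0.146). Their median was −0.15 without infected control library 3 and −0.44 without library 4. Without infected control library 1, mt-Atp8 (adjusted p = 0.0134) and mt-Co1 (0.0338) were called.

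Camera called 17 of the 30 lists after infection and fry kept 15 of them. The lists that missed the camera threshold were goblet cell and mucus (Muc2, Clca1 and Retnlb rose and Muc13 fell, 4 of 17, adjusted p = 0.382), tuft cell (3 of 14 rose, Alox5 and Avil among them, 0.0655), enteroendocrine cell (Tph1 rose, Chga and Chgb fell, 3 of 12, 0.129), crypt stem cell (Prom1 fell, 1 of 12, 0.787). So did plasma cell (Mzb1 and Irf4 rose, 2 of 6, 0.129), IL-17 and IL-22 axis (2 rose, Il22 and Ccr6, and 2 fell, Il22ra1 among them, of 8, 0.910), smooth muscle (0 of 14, 0.910) and fibroblast (Col1a1 and Timp1 rose, 2 of 14, 0.129). The last were enteric neuron and glia (0 of 14, 0.176), red blood cell (0 of 5, 0.155), immediate early (Hspa1a, Hspa1b and Dnajb1 rose, 3 of 14, 0.176), sialic acid metabolism (4 rose and 3 fell of 26; 0.787) and cholesterol synthesis (4 of 21 fell, Insig1 and Stard4 among them, 0.0728). Adjusted over the list alone, these lists had 4, 3, 3, 1, 2, 4, 0, 1, 0, 0, 3, 12 and 4 calls in the same order. The smooth muscle median (−0.03) and mean (0.03) differed in sign. The count of 4008 fell to 2537 without infected control library 3. It was 412 with the B cell list level and 38 with the adipose list level as a covariate, both added after the data were seen and both aligned with infection.

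**Figure D2:**
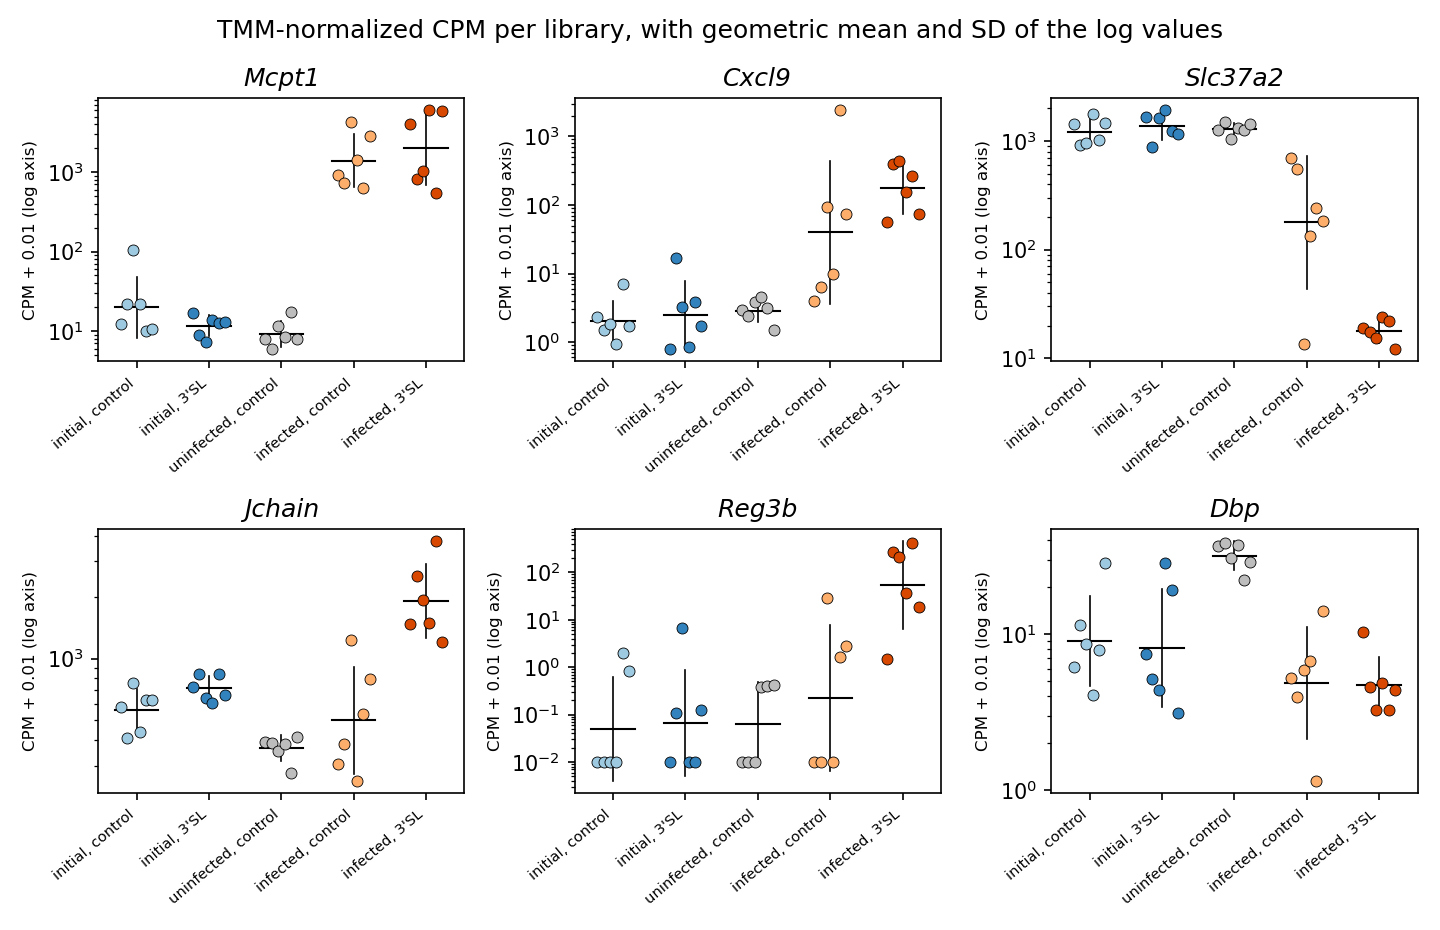
TMM-normalized CPM plus 0.01 (log axis) of Mcpt1, Cxcl9, Slc37a2, Jchain, Reg3b and Dbp in each library of the 5 groups (n = 6 each); the bar is the geometric mean and the line the SD of the log values. Slc37a2 lies between 12.0 and 24.1 CPM in infected 3'SL libraries and between 13.6 and 706 CPM in infected controls.

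The next question was what 3'SL does in infected mice. Against infected controls, 3326 of 15290 genes differed, 1506 higher and 1820 lower, with 154 and 551 of them by at least 2-fold. This count rests on a spread estimated over 18 libraries, among them the uninfected controls, which differed less from each other than the infected controls did. A fit of the 12 libraries compared alone called 1268 genes. On the first principal component the groups overlapped, as infected control libraries 3, 5 and 6 lay within the range of the infected 3'SL libraries. Absorptive colonocyte genes were lower in 13 of 20 cases (16 adjusted over the list alone; median −1.22; adjusted p = 0.392 with an estimated correlation). Slc37a2 (ENSMUSG00000032122) fell from 306 ± 267 to 18.4 ± 4.43 CPM (log2 −4.04 ± 0.58 SE, adjusted p = 0.000959), the cytochrome Cyp2c55 from 2923 ± 2207 to 184 ± 125 CPM (−3.97 ± 0.59). Slc37a2 was at 706, 558, 13.6, 134, 240.5 and 185 CPM in infected control libraries 1 to 6. The lowest fold changes by the rule were Trpv6 (ENSMUSG00000029868), 382-fold lower (95% interval 68.1 to 15129, from 369 against 1 counts), Ugt8a (−5.14 ± 0.91), Cyp4b1 (−5.09 ± 0.77), the zinc and manganese transporter Slc30a10 (−4.85 ± 0.73), the magnesium channel Trpm6 (−4.70 ± 0.55) and Ugt1a9 (−6.89 ± 2.27). The highest were the C-type lectins Reg3b (ENSMUSG00000071356, 4.82 ± 1.34) and Reg3g (3.22 ± 0.84), Prss22 (3.75 ± 0.94), Krt13 (2.95 ± 0.93), Clca4b (2.94 ± 0.80) and the tryptase Tpsb2 (2.70 ± 0.91). Reg3b was at 1.47 to 415 CPM with 3'SL and at 0 to 28.9 CPM in infected controls.

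Some of these values and calls rested on single libraries. Trpv6 was 86.1-fold lower without infected control library 1, which held 299 of its 369 counts. Without the same library Ugt8a was −4.43, Cyp4b1 −4.45 and Slc30a10 −4.17. Without infected control library 3, Reg3b was 7.47, Reg3g 4.53, Prss22 4.78, Krt13 4.51 and Clca4b 3.71, and without 3'SL library 5 Reg3b was 4.21 and Reg3g 2.51. Krt13 was 2.20 without 3'SL library 6 and Clca4b 2.04 without 3'SL library 2. Ugt1a9 was −7.55 and −7.57 without 3'SL libraries 3 and 4 and −5.54 without control library 2. Clca4b was lost without infected 3'SL library 2 (adjusted p = 0.0586) and Krt13 without 3'SL library 6 or infected control libraries 1, 2 or 4 (0.0554 to 0.103). Tpsb2 was lost without 3'SL libraries 1, 4 or 6 or control libraries 1, 2, 5 or 6 (0.0516 to 0.0912), and Ugt1a9 without any 3'SL library or control libraries 1 or 2 (0.0513 to 0.103). In a fit and filter of the 12 libraries compared alone, 1268 genes were called in place of 3326, and Reg3b (adjusted p = 0.0717), Reg3g (0.0599), Krt13 (0.0844), Clca4b (0.0643) and Tpsb2 (0.116) were not among them. With no filter on low counts, Tpsb2 (0.0592) and Ugt1a9 (0.0545) were not called. The count was 2168 without infected control library 1 and 2127 without library 2.

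Plasma cell genes were higher with 3'SL in 5 of 6 cases (6 adjusted over the list alone): Jchain (ENSMUSG00000067149), which links secreted immunoglobulins, went from 584 ± 372 to 2067 ± 951 CPM (1.84 ± 0.35, adjusted p = 0.00246), and Derl3 changed by 2.35 ± 0.46. All 26 cell cycle genes were higher (26, with Cdc20 0.89 ± 0.13, Plk1 0.66 ± 0.12), as were 9 of 16 macrophage genes (9, with C1qc 1.16 ± 0.20, C1qa 1.06 ± 0.19). These 3 lists had an adjusted p of 0.392 with an estimated correlation. T and NK cell genes were higher in 10 of 23 (10, with Tigit 1.77 ± 0.39, Nkg7 1.36 ± 0.38; 0.462 with an estimated correlation), MHC class II genes in 5 of 11 (6, with Ctss 0.67 ± 0.13, H2-Ab1 0.93 ± 0.27; 0.506), type 2 response genes in 2 of 14 (2, with Ccl8 1.75 ± 0.45, Arg1 2.14 ± 0.66; 0.555) and granulocyte genes in 2 of 12 (2, with Prg2, an eosinophil granule protein, 2.22 ± 0.49, Ly6g 2.69 ± 0.76; 0.555). The first number in each bracket is the count adjusted over the list alone and the last the adjusted p with an estimated correlation. H2-Ab1 was lost without infected control library 2 (0.0513), and Arg1 without 3'SL library 6 or control libraries 1, 2 or 4 (0.0527 to 0.0700). Arg1 was 2.78 without control library 6, and Prg2 2.90 and Ly6g 3.84 without control library 3. The type 2 list was lost without 3'SL library 6 or control libraries 1, 2 or 4 (0.0553 to 0.112) and the granulocyte list without control library 1 (0.0583). With the 12 libraries alone, Nkg7 (0.0584), H2-Ab1 (0.0665), Ccl8 (0.0528), Arg1 (0.0926) and Ly6g (0.0659) were not called.

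Interferon-gamma response genes gave a mixed picture: 2 of 31 were higher (0 adjusted over the list alone), Psmb8 by 0.99 ± 0.34 and Tbx21 by 1.25 ± 0.43, and camera placed the list higher although its median was −0.06 and its mean 0.05 (adjusted p = 0.568 with an estimated correlation). The median was 1.55 without infected control library 5, between −0.27 and −0.14 without any other infected control or 3'SL libraries 2 or 3, and 0.0331 and 0.0066 without 3'SL libraries 1 and 6. Both genes were called only in part of the alternatives: Psmb8 was lost without 3'SL libraries 2, 3, 5 or 6 or infected control libraries 1, 2 or 4 (0.0542 to 0.101), Tbx21 without 3'SL libraries 2, 3 or 5 or control libraries 1, 2 or 4 (0.0850 to 0.103), both with the 12 libraries alone (0.120 and 0.110), and both with no filter on low counts (0.0588 and 0.0543). Ifng (0.68 ± 0.97, adjusted p = 0.648), Nos2 (1.04 ± 0.95, 0.449) and Ido1 (1.77 ± 0.74, 0.0948) did not pass. Without infected control library 5 all 3 were called: Ifng at 3.50 (0.00458), Nos2 at 3.01 (0.0140) and Ido1 at 3.25 (0.00191). Ifng was at 10.5 CPM in that library, at 0 to 0.683 CPM in the other infected controls and at 0.835 to 7.05 CPM with 3'SL. Of the type I interferon genes 1 of 16 was higher (0 adjusted over the list alone), Oasl1 by 0.63 ± 0.22, and Oas1a was at 0.42 ± 0.27 (adjusted p = 0.591 with an estimated correlation). Oasl1 was lost without any of 3'SL libraries 2, 3 and 5 or control libraries 1, 2, 3, 4 and 6 (0.0592 to 0.111), with the 12 libraries alone (0.113) and with no filter on low counts (0.0549). Oas1a was called without control library 5 (0.00742). The list was lost without control libraries 1 or 4 (0.0552 and 0.0599). Of the remaining genes fixed by name, Il13 (1.02 ± 0.77, 0.349), Muc2 (−0.16 ± 0.23, 0.637), Retnlb (0.14 ± 0.36, 0.816) and Mcpt1 (0.79 ± 0.59, 0.351) did not pass. Retnlb turned to −0.0032, −0.16 and −0.0119 without 3'SL libraries 1, 4 and 6.

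Enteric neuron and glia genes were lower with 3'SL in 11 of 14 cases (12 adjusted over the list alone; Snap25 −1.69 ± 0.28) and enteroendocrine genes in 6 of 12 (7, with Chga −0.87 ± 0.22, Chgb −0.74 ± 0.19), both with an adjusted p of 0.392 under an estimated correlation. Fatty acid oxidation genes were lower in 10 of 20 (13, with Pdk4 −1.91 ± 0.36; 0.462). Of the tight junction genes 4 of 16 were lower (Cldn23 and Tjp1 among them) and 1, Cldn2, higher (5, with Cldn8 −3.11 ± 0.51, Ocln −0.75 ± 0.19; 0.568). Of the circadian clock genes 3 of 15 were lower (Npas2 among them) and 1, Bhlhe41, higher (5, with Nr1d2 −0.62 ± 0.15, Cry1 −0.58 ± 0.16; 0.506), and of the crypt stem cell genes 2 of 12 were lower (3, with Axin2 −0.32 ± 0.09, Ascl2 −0.46 ± 0.14; 0.555). Of the smooth muscle genes 1 of 14 was lower (0, with Myh11 −0.80 ± 0.27, with Mylk at −0.54 ± 0.19; 0.568). Of the 13 mitochondrially encoded genes 3 were lower (mt-Nd1 among them; 11; mt-Co1 −0.82 ± 0.24, mt-Co3 −0.58 ± 0.20; 0.559). On the higher side, 4 of 21 cholesterol synthesis genes passed (Fdps and Mvd among them; 9; Srebf2 0.22 ± 0.07; 0.568), and no member of the B cell list (0, with Fcrla 0.68 ± 0.32, Cd79a 0.59 ± 0.30; 0.650) or the red blood cell list (2, with Hbb-bs 0.61 ± 0.23, Hbb-bt 0.97 ± 0.37; 0.392). In brackets the first number is the count adjusted over the list alone and the last the adjusted p with an estimated correlation. The lower lists moved beside a lower mitochondrial share of counts, 5.98% against 9.07%.

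Several of these calls depended on single libraries. Ascl2 was lost without infected control libraries 1 (adjusted p = 0.0613) or 4 (0.0624), mt-Co1 without the same 2 (0.0559 and 0.0547), and mt-Co3 without any of 3'SL libraries 1, 2, 3, 5 and 6 or control libraries 1, 2 and 4 (0.0502 to 0.121). Myh11 was lost without 3'SL libraries 2, 3, 5 or 6 or control libraries 1, 2 or 4 (0.0539 to 0.117) and Srebf2 without 3'SL libraries 3, 5 or 6 or control libraries 1 or 4 (0.0527 to 0.0741). DESeq2 called Mylk (0.0298), Hbb-bs (0.0456) and Hbb-bt (0.0415). Calls were gained for Mylk without 3'SL libraries 1 or 4 or control libraries 5 or 6 (0.0133 to 0.0456), for Hbb-bs without 3'SL libraries 1 or 4 (0.0282 and 0.0381), for Hbb-bt without 3'SL library 4 or control library 5 (0.0386 and 0.0378), and for Cd79a without control library 6 (0.0498). Among lists, the B cell list was lost without 3'SL libraries 1, 5 or 6 or control libraries 1 or 4 (0.0603 to 0.255), the clock list without 3'SL library 3 or control libraries 1, 2, 3 or 6 (0.0501 to 0.0802) and the crypt stem cell list without 3'SL libraries 2 or 6 or control libraries 3 or 4 (0.0532 to 0.0832). The cholesterol (0.0779) and red blood cell (0.0663) lists were lost without control library 6, and the tight junction list without 3'SL library 1 (0.0707) or control library 1 (0.0777). With the 12 libraries alone, Chga (0.0586), Chgb (0.0592), Ocln (0.0562), Nr1d2 (0.0508), Cry1 (0.0530), Axin2 (0.0666), Ascl2 (0.0729), Myh11 (0.111), mt-Co1 (0.0769), mt-Co3 (0.122) and Srebf2 (0.0844) were not called.

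Camera called 21 of the 30 lists for 3'SL in infected mice, and fry kept 10 of them. The lists that missed the camera threshold were mast cell (Tpsb2 higher, 1 of 11, adjusted p = 0.223), goblet cell (Agr2 higher, Zg16, Tff3 and Klk1 lower, 4 of 17, 0.0929), tuft cell (0 of 14, 0.201) and antimicrobial and acute phase (Reg3b, Reg3g and Pglyrp1 higher, 3 of 14, 0.192). So did IL-17 and IL-22 axis (4 of 8 lower, Ccl20, Il22ra1 and Il22ra2 among them, 0.0595), fibroblast (Pdgfra and Postn lower, 2 of 14, 0.529), adipose tissue (0 of 11, 0.0953), immediate early (Fosb lower, 1 of 14, 0.957) and sialic acid metabolism (2 higher and 7 lower of 26; 0.637). Adjusted over the list alone, they had 0, 4, 0, 3, 4, 0, 0, 1 and 9 calls in the same order. The sialic acid list had a median of 0.04 and a mean of −0.15, and the immediate early list a median of 0.04 and a mean of −0.12.

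**Figure D3:**
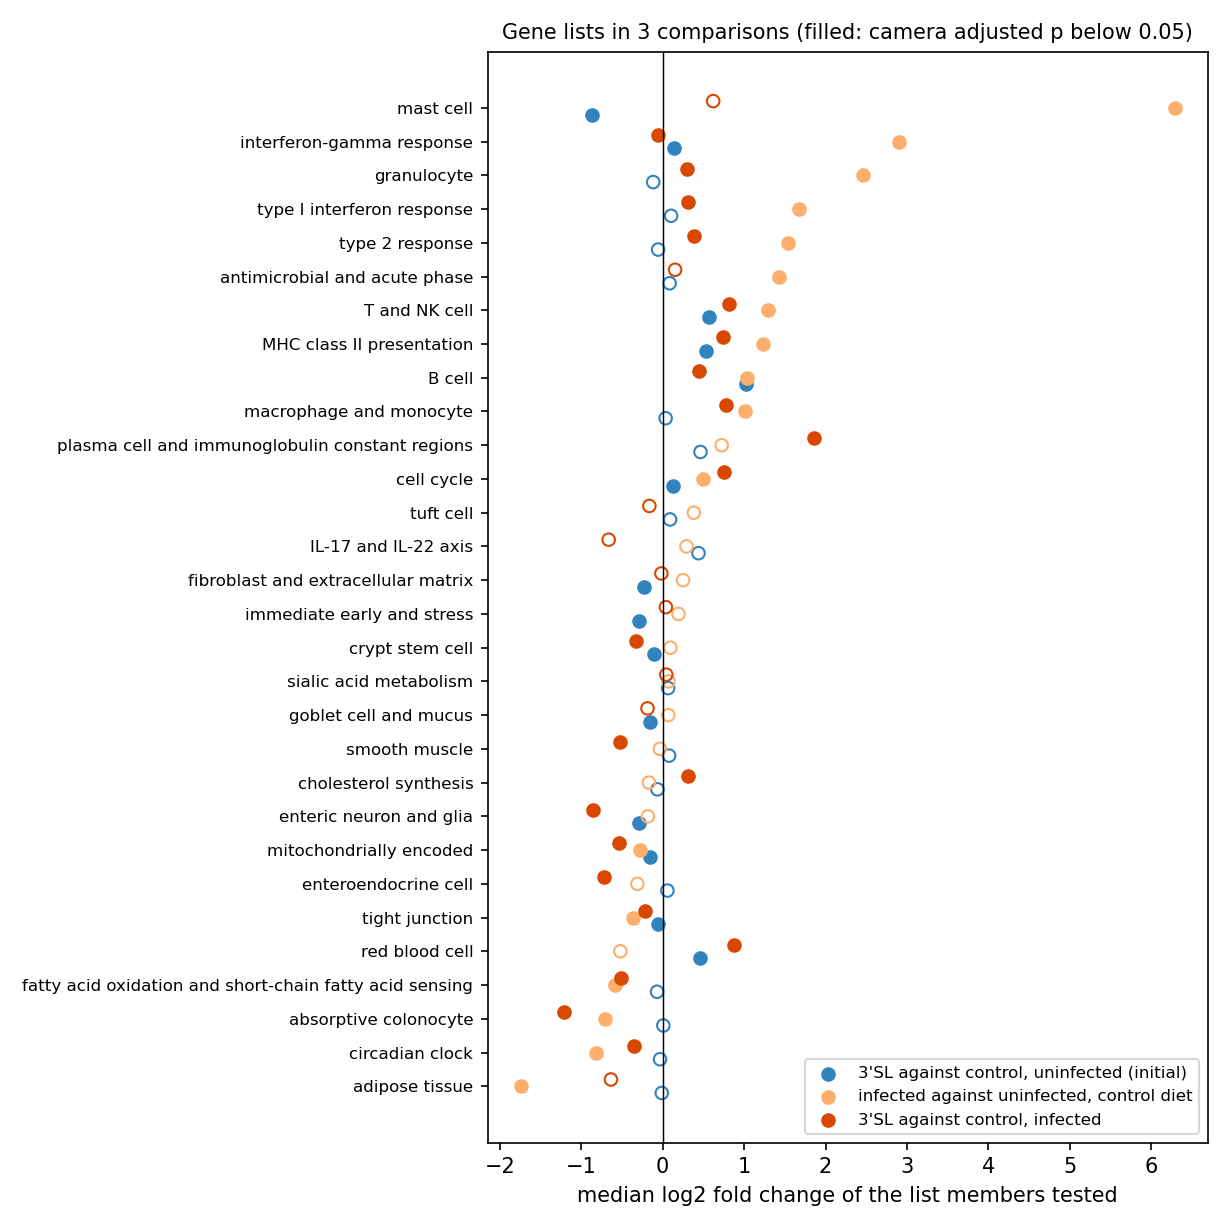
Median log2 fold change of the tested members of each of the 30 gene lists in 3 comparisons (colours); filled points have a camera adjusted p under 0.05 with the preset correlation. The mast cell list lies at 6.29 after infection on the control diet and the adipose list at −1.75; no call was kept with an estimated correlation.

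Infected mice on 3'SL were also set against the uninfected controls of the same experiment, a contrast that holds infection and 3'SL together. It called 9023 of 15290 genes, 4727 higher and 4296 lower. The highest by the rule were Cma2 (11.75 ± 1.23), Reg3b (9.66 ± 1.82) and Pla2g4c (9.54 ± 1.17). The lowest were Trpv6, 10900.2-fold lower (95% interval 1956 to 430577, from 9889 against 1 counts), Ugt1a9 (−7.70 ± 2.28) and Cyp4b1 (−7.11 ± 0.83). Ugt1a9 was lost without uninfected control library 5 (−3.37, adjusted p = 0.127), which held 46.1 CPM, and was −8.36 and −8.38 without infected 3'SL libraries 3 and 4. Reg3b was 9.06 without infected 3'SL library 5 and Pla2g4c 10.52 without uninfected control library 1. The 1 count of Trpv6 lay in infected 3'SL library 1. All 31 interferon-gamma response genes (adjusted p = 0.383 with an estimated correlation), all 26 cell cycle genes and all 23 T and NK cell genes were higher, and 15 of 20 absorptive colonocyte genes were lower and 2 higher (each 0.301). Adjusted over the list alone the calls were 31, 26, 23 and 17. Camera called 21 lists, with adjusted p-values of 0.301 to 0.683 under an estimated correlation. The count was 4197 with the B cell list level and 1549 with the adipose list level as a covariate.

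Fold changes of infection on the control diet and of 3'SL in infected mice correlated across genes (r = 0.52 over 15290 genes, which are not independent replicates). They share the infected controls with opposite sign, and simulated groups without any effect gave −0.50. The covariance was 0.175 against a simulated −0.0347, a difference of 0.210, and r was 0.53 with the infected controls split between the comparisons. Genes called higher in both numbered 453 against 239 for independent lists, and genes called lower in both 565 against 188. There were 36 and 28 genes that moved in opposite directions, against 289 and 156. For infection on the control diet and infection with 3'SL, which share the uninfected controls, r was 0.88 (simulated 0.50, split 0.83) and the covariance 0.542 against 0.0352. In all, 2257 genes were called higher in both (750 for independent lists) and 1461 lower in both (445). The shared controls raise such overlaps by themselves, and no overlap was simulated.

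The difference between the 3'SL effect in infected and in uninfected mice was tested over all 30 libraries. Infection and experiment cannot be told apart in this contrast. It called 1307 of 15543 genes, 457 positive and 850 negative. Most positive by the rule, which takes called genes with a mean CPM of at least 1, were Krt13 (6.54 ± 1.69, adjusted p = 0.0170), Pla2g4c (6.24 ± 1.46, 0.00937) and the neutrophil marker Ly6g (4.28 ± 1.15, 0.0213). Part of each difference lay in the initial experiment. In infected mice alone the 3'SL effect was 2.95 for Krt13 and 2.69 for Ly6g. Pla2g4c went from 28.0 ± 46.4 CPM in initial controls to 0.79 ± 0.30 CPM with 3'SL. In infected mice it went from 697 ± 775 to 1495 ± 1291 CPM. The rule named Trpv6 (adjusted p = 0.0139), Cyp4f15 (0.0119) and Rnf212 (0.000440) as most negative by fitted value. These 3 genes had 1, 0 and 2 counts in infected 3'SL libraries, so their fitted differences depend on the prior count and give no order. In infected mice Trpv6 was 382-fold lower with 3'SL (95% interval 68.1 to 15129), Cyp4f15 at least 15.5-fold lower and Rnf212 76.1-fold lower (95% interval 20.7 to 634). Trpv6 was 86.1-fold lower without infected control library 1, and Cyp4f15 at least 7.42-fold lower without library 2. Absorptive colonocyte genes had 12 of 20 negative calls (13 adjusted over the list alone) and macrophage genes 5 of 16 positive ones (Cd68, C1qa, C1qb, C1qc and Ms4a7; 8), both with an adjusted p of 0.389 under an estimated correlation. Camera called 17 of the 30 lists here, and none was kept with an estimated correlation (0.389 to 0.688). For the interferon-gamma list camera pointed upward although its median was −0.28 and its mean −0.30. Ly6g was lost without initial control library 3 (3.74, adjusted p = 0.0531) and was 5.44 without infected control library 3. Pla2g4c was 4.66 without initial control library 3, which held 121 CPM, and 6.99 without infected control library 3. Krt13 was 5.82 without infected 3'SL library 6, 8.08 without infected control library 3, 7.57 without initial 3'SL library 1 and 5.90 without initial control library 1. The count was 691 with only the 4 groups in the contrast, 2720 with the B cell list level as a covariate, 842 without infected control library 1, 810 without library 2 and 2206 without library 5.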

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

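The tests of time of day, epithelial share, lymphoid tissue in infected mice, infection response and 3'SL on B cell genes were chosen after the results they weigh were seen; the splits of the samples and the test of follicle tissue were set before.

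Single libraries stood apart from the other 5 of their group in 19 of 433 groups tested by Dixon's gap test, where chance gives about 22. In the initial controls, library 3 held the highest Mcpt1 (104 CPM), Mcpt2 (49.6 CPM), Ms4a2 (1.69 CPM) and Retnlb (308 CPM), and library 2 the highest Fosb (14.1 CPM). In the initial 3'SL group, library 2 was lowest in Muc2 (712 CPM), library 4 in Hbb-bs (2.82 CPM) and library 6 in Hba-a2 (0.565 CPM). In the uninfected controls, library 5 held 46.1 CPM of Ugt1a9 against at most 0.555 in the others, library 3 held 19.7 CPM of Cd3e, library 6 alone had Il13 (0.0556 CPM), library 4 had Fcer1a at 0 and library 1 had Mcpt9 and Itln1 at 0. Infected control library 5 was highest in Oasl1 (73.2 CPM). Among infected 3'SL libraries, library 4 was highest in Ocln (73.3 CPM) and Tjp1 (149.6 CPM) and alone had Rnf212 (0.0570 CPM), and library 1 alone had Trpv6 (0.0253 CPM).

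The log2 effect of 3'SL differed between infected and uninfected mice by the test of the difference for 25 of the genes named here for 3'SL in infected mice, and infection cannot be told apart from experiment in it. These genes were named for their 3'SL effect in infected mice, which is part of the difference, so their number is no further support. Over all genes the test called 1307 of 15543 (8.41%). Prss22 had no count in initial 3'SL libraries, so its fitted 10.47 depends on the prior count, and the difference was at least 8.41 with that group set at 3 counts. Trpv6 had 1 count in infected 3'SL libraries, so its fitted −7.49 depends on the prior count too, and it was −5.32 without infected control library 1 and −8.67 without infected 3'SL library 1. The difference was also positive for Krt13 (6.54), Ly6g (4.28), Clca4b (3.77), Tnfrsf17 (1.65), Jchain (1.49), Cd68 (1.27), C1qc (1.04), C1qa (0.96), Cdc20 (0.72) and Plk1 (0.59). It was negative for Ugt8a (−5.19), Slc30a10 (−5.12), Cyp4b1 (−4.99), Trpm6 (−4.84), Slc37a2 (−4.22), Cyp2c55 (−4.01), Cldn8 (−3.16), St3gal5 (−2.56), Slc26a3 (−2.03), Pdk4 (−1.83), Snap25 (−1.35), Neu1 (−0.86) and Chgb (−0.78).

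Absorptive colonocyte genes were lower in infected mice on 3'SL. A lower share of epithelium would lower goblet and stem cell genes alike. The absorptive level minus the mean of those lists was also lower (0.20 ± 0.12 SD against 1.10 ± 0.50, n = 6 each, two-sided exact permutation p = 0.00649). Those lists were chosen after their medians (−0.19 and −0.32, against −1.22) were seen, so this p is no separate support. Enteroendocrine genes (median −0.73) and tuft cell genes (−0.16) were not used. Absorptive genes fell more than goblet and stem cell genes, and a lower share of epithelium stays open as part of the cause. With the B cell list level as a covariate, 13 of the 13 lower genes stayed lower (median −1.81 before, −1.58 with it). That does not decide about more lymphoid tissue. No B cell gene was called in this comparison (0 of 14), so the covariate could remove little. The plasma cell and the T and NK cell lists, which were higher with 3'SL, were not used. With the infected controls split between the comparisons, all 13 (100%) had the sign of their infection change, against 83.9% of the 1820 genes lower with 3'SL and 69.4% of all 15290 tested, so the share is high for lower genes in general. The 13 were picked for being lower with 3'SL. The share was 87.75% over all 20 tested absorptive genes and 65% over the other 7. A stronger infection response on 3'SL may be an explanation and stays open, as does a direct effect of 3'SL, which was not tested apart from it.

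Circadian clock genes were lower in infected mice on the control diet. The 5 genes that peak with Arntl had a median log2 fold change of 0.50 and the 7 that peak with Dbp of −1.43, so a harvest at another time of day may account for it; the times are not in the labels. Of the 12 uninfected libraries of the initial experiment, 9 had Dbp at or below the highest infected control, so time and infection cannot be told apart here.

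B cell genes varied widely between the libraries of the initial experiment. The level of 8 follicle markers followed that of the B cell list over 12 libraries (Pearson r = 0.976, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.965, p = 2e-05; 0.972 among controls, 0.981 with 3'SL). Without the 2 libraries farthest from the median r was 0.962, no other such relation was computed, and none of the 8 markers is in another list. The marker Cxcl13 was at 23.0 ± 27.6 CPM in controls and 46.9 ± 43.8 CPM with 3'SL, and lymphoid follicles in some samples may account for the spread. The difference between the 3'SL and control libraries had an exact permutation p of 0.0996 (n = 6 each), which leaves an effect of 3'SL open.

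Splits of the same libraries numbered 100, the real one included. For infection on the control diet 1 called as many genes (4008, highest other 3020). For infection with 3'SL 1 called as many (9023, highest other 5617), as did 1 for the difference of the 3'SL effects (1307, highest other 913). That 1 was the real split each time. Its share is under the 0.05 set for excluding chance. The real split was not drawn and reaches its own count by construction. The exact 95% interval of 1% of 100 splits is 0.0253% to 5.45%, but it treats the real split as a draw. Chance is excluded by that threshold only. For 3'SL in infected mice 3 splits called as many (3326 for the real one). That is under the share of 0.05 set for excluding chance. The exact 95% interval of 3% of 100 splits is 0.623% to 8.52%, and it too treats the real split as a draw. The threshold is met, but chance stays possible for this comparison. The 2 other splits called more (3946 and 3692), which points to a structure among these libraries. Infected control libraries 1, 2 and 4 lay apart from 3, 5 and 6 on the first principal component. The count was 2168, 2127 and 2432 without library 1, 2 or 4, and 4186, 4614 and 3710 without library 3, 5 or 6. Whether the 2 splits follow this division, and its source, were not tested. For 3'SL in uninfected mice the splits decide nothing about chance, since any of the 100 reaches the 0 genes of the real one. The highest other called 961, which points to a structure of the samples whose source was not tested.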

How the results depend on the processing

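Covariates for B cell and adipose list levels were chosen after seeing the data; the other alternatives were set before. Without each library in turn, counts ranged from 0 to 0 for 3'SL in uninfected mice, 2537 (without infected control 3) to 5546 (without infected control 1) for infection, 2127 (without infected control 2) to 4614 (without infected control 5) for 3'SL in infected mice, 8426 to 9258 for infection with 3'SL, and 810 to 2206 (without infected controls 2 and 5) for the difference of the effects. DESeq2 called 5 genes for 3'SL in uninfected mice. With only the groups compared, 1268 genes were called for 3'SL in infected mice and 691 for the difference. With the B cell level as a covariate the counts were 412 for infection, 4197 for infection with 3'SL and 2720 for the difference; with the adipose level they were 38 and 1549 for infection and infection with 3'SL. Both levels differ with infection, so these fits share its effect. The other 28 count alternatives stayed within 1.5 times.

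In uninfected mice the B cell covariate reversed Psmb8 (−0.0553), Socs1 (−0.19), H2-DMb1 (−0.0329), H2-Ab1 (−0.28), Prom1 (0.0111), Bank1 (−0.17), Spib (−0.31), Nos2 (−0.11) and Reg3g (−0.16); Ido1 ranged from −0.0234 (without 3'SL library 4) to 0.24 (without control 2). For infection the adipose covariate reversed Adipoq (0.27), Retn (0.66), Cfd (1.23), Oasl2 (−0.0599), Isg15 (−0.15), Nos2 (−1.30) and Ido1 (−0.81). For 3'SL in infected mice Retnlb ranged from −0.16 (without 3'SL library 4) to 0.32 (without 3'SL library 2). The cause of these changes was not tested. Of the named-gene values outside leave-one-out, 1410 kept direction and side of the threshold, 148 lost a call, 15 gained one and 17 reversed. With RLE factors or DESeq2 0 of these calls were lost. Genes to which DESeq2 gave no adjusted p were left out of this check and could not count as lost. Depth limits the fold changes of genes near 0 counts.

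Replicate numbers did not pair the mice: of 24 pairs of same-numbered libraries, 8 correlated above 0.1 (range −0.54 to 0.61) and 2 matched their own number best. With the replicate block the counts were 0, 3499, 3214, 8911 and 1015 in the order above, Retnlb for 3'SL in infected mice turned to −0.0707, and 10 named calls were lost. They were S100a9 (adjusted p = 0.0515), Cfd (0.0514), Ifng (0.0581) and Nos2 (0.130) for infection, Tpsb2 (0.101), Ugt1a9 (0.0870), Ascl2 (0.0518), mt-Nd1 (0.0668) and Il22ra1 (0.0581) for 3'SL in infected mice, and Pla2g4c (5.20, 0.0504) for the difference of the effects. Ido1 (0.0471), Prom1 (0.0437) and Mylk (0.0416) were gained for 3'SL in infected mice.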

Other observations

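The genes named here were chosen after their values were seen, and no further test was run on them.

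Sialic acid is part of 3'SL, and the list of its metabolism held genes that moved both ways. Infection on the control diet raised the sialyltransferase St3gal4 from 14.9 ± 2.36 to 142.6 ± 105 CPM (log2 3.27 ± 0.43 SE, n = 6 each, adjusted p = 0.000266) and Npl, which breaks down free sialic acid (2.10 ± 0.31, 0.000514). St3gal6 (1.33 ± 0.24) and St8sia4 (1.02 ± 0.26) rose, while the sialidase Neu1 (−0.64 ± 0.15, 0.00737), St3gal5 (−1.03 ± 0.35, 0.0390) and Nans (−0.23 ± 0.07, 0.0208) fell. St3gal5 was not called without any of 10 of the 12 libraries compared (0.0526 to 0.0835), all but infected controls 1 and 2, nor with only the groups compared (0.0582) or no filter (0.0516). In infected mice 3'SL went with lower St3gal5 (−2.41 ± 0.37, 0.000986), and lower Neu1 (−0.75 ± 0.15, 0.00348), and with higher St6gal1 (0.78 ± 0.20, 0.0135; 0.0557 with only the groups compared).

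Members of the IL-17 and IL-22 list were lower in infected mice on 3'SL. The chemokine Ccl20 fell from 9.85 ± 1.93 to 3.97 ± 1.71 CPM (−1.29 ± 0.24, n = 6 each, adjusted p = 0.00244). The IL-22 binding protein Il22ra2 fell by 1.93 ± 0.52 on the log2 scale (0.0155; 0.0670 with only the groups compared). The receptor chain Il22ra1 was lower (−0.87 ± 0.25, 0.0211), but not called without infected control libraries 1 (0.0570) or 2 (0.0514) or with only the groups compared (0.0778). Fry gave the list an adjusted p of 0.00748, while camera gave 0.0595.

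The uninfected controls of the second experiment were compared with the initial controls in a separate fit of 12 libraries, which called 144 of 14933 genes, 66 higher and 78 lower, with 2660 at an unadjusted p under 0.05. Clock genes were among them, with Nfil3 (−1.39), Arntl (−0.74) and Cry1 (−0.63) lower and Per3 (1.35) and Nr1d2 (0.67) higher in the second experiment. Infection on the control diet moved each the other way (2.51, 0.57, 0.50, −1.43 and −0.86 in that order). Npas2 was lower too (−0.46) but stood at −0.02 after infection. Both comparisons share these uninfected controls, which by itself favours opposite signs.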
